A study of Rattus norvegicus with 6 samples.

How the data were processed

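Left ventricular RNA of male Wistar rats was hybridised to 6 Affymetrix expression arrays, 2 for each of 3 diets, each with RNA pooled from 5 rats, per the labels. Complementary RNA was made from 5 µg of total RNA with poly-A control transcripts spiked in, per the labels' protocols. The value table holds log2 expression values deposited by the authors for 31099 probe sets, made with RMA in R 2.11.0 per the submitters' processing notes. As a method RMA sets arrays to a common distribution, so differences in overall RNA level between arrays are not measured. The steps before RMA and the genome build are not given in the sources used here, and no coordinates are printed. The authors also deposited mean log2 values per diet, log2 differences, p-values and Benjamini-Hochberg adjusted p-values for the 3 comparisons, and a list of 66 probe sets. The test behind the authors' p-values is not given in the sources used here. A limma fit that kept the control probe sets differed from the authors' p-values by at most 5.39e-08.

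Groups and replicate names came from the labels. The labels used here name no batch. A replicate is a pool of 5 rats, so p-values measure the spread between 2 pools per diet and not that between rats. Of the probe sets, 57 Affymetrix controls were left out of the tests, which left 31042. Gene symbols came from the platform annotation, updated through Entrez identifiers with the RefSeq gene table of assembly GRCr8. Of the tested probe sets, 20826 had 1 symbol, 436 had several and 9780 had none, and the last 2 kinds were not named. For lists and named genes, the probe set with the highest mean stood for each of 14217 genes. The remaining probe sets of named genes were set beside it as an alternative.

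Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) on the deposited log2 values, with 1 mean per diet and all 6 arrays sharing 1 estimate of the spread. The fit had 3 residual degrees of freedom and 5.28 prior degrees of freedom. Adjusted p is by Benjamini-Hochberg over all tested probe sets per comparison, with a threshold of 0.05. An F test over the 3 diets called 1 probe set, with a lowest adjusted p of 0.0282. Fold values are 2 to the power of the log2 difference. Before the data were examined, 44 gene lists were fixed, 31 of programmes and 13 of cell type markers, and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 44 lists. Camera with an estimated correlation called 0 lists in each comparison. The test fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, called 0, 3 and 0 lists in Western against Control, Western plus DHA against Control and Western plus DHA against Western.

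The named genes followed a rule set at the same time. Per comparison it took representative probe sets at or above the median level of all probe sets in the higher diet, with both arrays of one diet above both of the other, and named the 10 per direction with the largest log2 difference among those that passed the test. Where fewer passed, the rule was filled up to 8 per direction by smallest p among genes with an absolute log2 difference of at least 0.5, reported as not passing. Genes named only by a locus or clone number were skipped. It also named a fixed panel of heart, lipid and clock genes, of which 17 are given and an item is not reported here, and of each described list up to 6 passing members or otherwise up to 4 with the smallest p. The called Myh7 probe set was named outside this rule, after its values were seen.

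The steps were tested on simulated data with 31042 probe sets and 200 changed probe sets in each of 10 simulations. For Western plus DHA against Control, 11.5% of changes of 0.5 on the log2 scale were recovered, 95.2% of changes of 1 and 99.8% of changes of 2. The noise was drawn independently for each probe set with moderated spreads, so these shares need not hold for the real arrays. There a log2 difference of 1.96 for Pik3c2g did not pass the test, while one of -1.96 for a Myh7 probe set did. A list shifted by 0.3 among 14217 genes was called in 10 of 10 simulations, and an unshifted list in 0 of 10, while other, unshifted lists were called 5 and 2 times in total. Genes were drawn independently here too, so these simulations cannot show how often camera calls lists whose genes are correlated. Alternatives fixed beforehand were a replicate block, removal of dim probe sets, quantile normalization again, median centring, an intensity trend or robust prior, array weights, fits of 4 arrays, representative probe sets alone, an adjusted p under 0.1, other list tests, the mean of a gene's probe sets, Spearman correlation, and leaving out each array. Added after the data were seen were cyclic loess normalization and a fit without Control 1 and Western plus DHA 2 together, the arrays whose deviations from the gene means opposed each other with r = -0.627 across probe sets. Simulations of overlap, sign and r with 1 array left out for unchanged groups with shared controls were added then too, 200 each, with moderated spreads, and each probe set's own spread gave mean overlaps of 112 and 112. The interquartile ranges of Control 1 and Western plus DHA 2 were 3.70 and 3.47, the widest and the narrowest of the 6 arrays.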

Results

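Messenger RNA was measured in left ventricular heart tissue of male Wistar rats that were fed 1 of 3 diets for 12 weeks from 6 weeks of age, after an overnight fast before collection. The diets were a control diet (Control), a Western diet (Western) and a Western diet with added docosahexaenoic acid (Western plus DHA), a long-chain polyunsaturated fatty acid of fish oil. Each diet group held 10 rats, and each of its 2 arrays was hybridised with RNA pooled from 5 rats. The design text states that the dietary treatment was meant to bring about left ventricular hypertrophy with few other disorders. The 6 arrays had median log2 values between 5.33 (Western plus DHA 2) and 5.36 (Western plus DHA 1). The correlation across probe sets between the 2 arrays of a diet was 0.993 for Control, 0.996 for Western and 0.993 for Western plus DHA, where probe sets are not independent replicates. The number of arrays limits the precision, and the median standard error of a log2 difference between diets was 0.144. All errors below are standard errors from the limma fit unless named SD, with n = 2 pools per diet.

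The comparison of Western with Control asked what the Western diet did to the left ventricle. Carbonic anhydrase Car3, an abundant enzyme of fat and slow muscle, gave the smallest p of the genes named by the rule, at 6.85 ± 0.0702 (SD) in Western against 5.11 ± 0.188 (SD) in Control, a log2 difference of 1.74 ± 0.223. The other, dimmer probe set of Car3 differed by 0.18. S100a9, a calcium-binding protein of neutrophils, stood 0.96 ± 0.151 higher in Western, and the acyl-CoA thioesterase Acot1 stood 0.69 ± 0.137 higher. Retsat (retinol saturase) had a log2 difference of -0.83 ± 0.178 and the cholesterol exporter Abca1 one of -0.77 ± 0.177. None of these genes passed the test. The limma test called 0 of 31042 probe sets at an adjusted p under 0.05, with a lowest adjusted p of 0.609, and 877 probe sets lay under an unadjusted p of 0.05 where chance gives 1552.1. Of these 57.1% were higher in Western, against 47.1% with quantile normalization again, 40.7% without dim probe sets, 41.8% after cyclic loess, 42.2% without Control 2 and 70.5% with representative probe sets. There were 2809 such probe sets without Control 2, 535 without Western 1 and 523 without Western 2.

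Of the other genes named for Western against Control, log2 differences above 0 were 0.91 for Pik3c2g, 0.51 for the alpha globin gene Hba-a3, 0.74 for Dpep1, 0.62 for Endou and 0.73 for Rnf6. Differences below 0 were -0.57 for Lrp6, -0.51 for Phlda1, -0.63 for the macrophage gene Adgre1, -0.54 for Tmem50b, -0.70 for Card9 and -0.61 for Fndc5. Other probe sets differed by 0.48 and 0.61 for Dpep1, by -0.02, -0.34 and -0.76 for Abca1 and by 0.16 for Col1a1. The natriuretic peptide genes, which the ventricle expresses under load, differed by 0.33 ± 0.391 for Nppa and 0.34 ± 0.188 for Nppb. In the fixed panel the lipid genes differed by 0.49 for the desaturase Scd, 0.29 for Angptl4, 0.29 for the fatty acid transporter Cd36, 0.21 for Ucp3, 0.03 for Cpt1b, -0.05 for Pdk4 and -0.08 for Fasn. The collagen genes differed by -0.56 for Col1a1 and -0.10 for Col3a1. The muscle genes differed by 0.06 for Myh6, -0.09 for Myh7, -0.18 for Acta1 and 0.02 for Ankrd1, and the clock genes by -0.18 for Dbp and -0.02 for Bmal1. The other, dimmer probe set of Myh7 differed by -0.40, and by -0.47 to -0.34 when 1 array was left out. Of the 34 probe sets named for this comparison, 22 changed by more than 1.5 times or changed sign when 1 array was left out. The difference of Fndc5 was -0.22 without Control 1 and -1.01 without Control 2, that of Tmem50b -0.29 and -0.79, that of Adgre1 -0.37 and -0.90, that of Phlda1 -0.31 and -0.70, and that of Card9 -1.08 and -0.32. Rnf6 had 0.47 and 0.98, Cd36 0.02 and 0.57, Angptl4 0.05 and 0.53, and Nppb 0.17 without Western 2. Every gene of this paragraph had an adjusted p of 1, and the Scd probe set, at 3.91 in Western, was dim.

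Camera called 4 of the 44 gene lists in Western against Control at its preset correlation. The hypertrophic and fetal list was not among them, with a median log2 difference of -0.02. The neutrophil list was higher, with a median log2 difference of 0.23 over 7 measured members (adjusted p = 0.00139, and adjusted p = 0.899 with an estimated correlation). Its leading members were S100a9, S100a8 (0.58 ± 0.16) and the collagenase Mmp8 (0.37 ± 0.13), and 0 members passed over all probe sets while 3 were higher at an adjusted p under 0.05 when adjusted over the list alone. The adipocyte list was higher, with a median of 0.09 over 12 members (adjusted p = 0.0245, and adjusted p = 0.899 with an estimated correlation), led by Car3, the adipokine Adipoq (0.74 ± 0.18) and the lipid droplet gene Cidec (0.43 ± 0.16), with 0 members passing over all probe sets and 2 higher when adjusted over the list alone. The glucocorticoid and fasting list was lower, with a median of -0.13 (adjusted p = 0.0245, and adjusted p = 0.931 with an estimated correlation), led by Ddit4 at -0.43 ± 0.12, with 14 of 19 members below 0. The immediate early list was lower, with a median of -0.16 (adjusted p = 0.0325, and adjusted p = 0.931 with an estimated correlation), led by Egr1 at -0.58 ± 0.27, with 15 of 19 members below 0. In both lists 0 members passed, also when adjusted over the list alone. No list of these 4 was called in all 6 fits that left out 1 array. The neutrophil call was lost without Control 1, the adipocyte call without Control 2, and the glucocorticoid and immediate early calls without Control 1 or Western 1. The highest adjusted p was 0.193 for neutrophils, 0.520 for adipocytes, 0.758 for the glucocorticoid list and 0.414 for the immediate early list. Medians lay between -0.39 (without Control 2) and 0.09 (without Control 1) for immediate early genes and between -0.21 (without Control 2) and -0.03 (without Control 1) for glucocorticoid genes. The adipocyte median was 0.14 without Western 2. Control 1 had the largest log2 difference between 3' and 5' probe sets for the poly-A and Gapdh controls, though not for beta-actin (values below). Whether this bears on the lists of this comparison was not tested.

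The comparison of Western plus DHA with Control asked how the ventricle on the supplemented diet differed from that on the control diet. Myh7, the slow beta isoform of the cardiac myosin heavy chain and a classic marker of the fetal programme, fell in Western plus DHA. The dimmer of its 2 probe sets read 10.04 ± 0.0899 (SD) in Control and 8.08 ± 0.176 (SD) in Western plus DHA, so it fell by 1.96 ± 0.137 on the log2 scale, a 3.90-fold lower level (limma adjusted p = 0.0119). This probe set was singled out after its values were seen. The brighter probe set of Myh7 differed by -0.99 ± 0.145, with an adjusted p of 0.499, and did not pass the test. The limma test called this 1 probe set of 31042, with 0 higher and 1 lower. With array weights 1993 probe sets lay under an unadjusted p of 0.05. In the main fit 2752 probe sets did, where chance gives 1552.1 if all diets share 1 spread. Of these 47.1% were higher in Western plus DHA, against 28.7% without dim probe sets, 37.3% after cyclic loess, 53.4% without Western plus DHA 2 and 54.1% with representative probe sets. There were 1314 such probe sets without Control 1 and 4955 without Control 2. The Myh7 call was lost in 5 of the 6 fits that left out 1 array, with adjusted p values of 0.355 without Control 1, 0.0532 without Control 2, 0.0838 without Western 1, 0.0838 without Western 2 and 0.172 without Western plus DHA 2, while its log2 difference stayed between -2.09 and -1.84. It was lost too without Control 1 and Western plus DHA 2 together (adjusted p = 0.508) and when only the 4 arrays compared were fitted (0.0838). Over all alternatives its adjusted p lay between 0.00408 and 0.508.

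**Figure D1:**
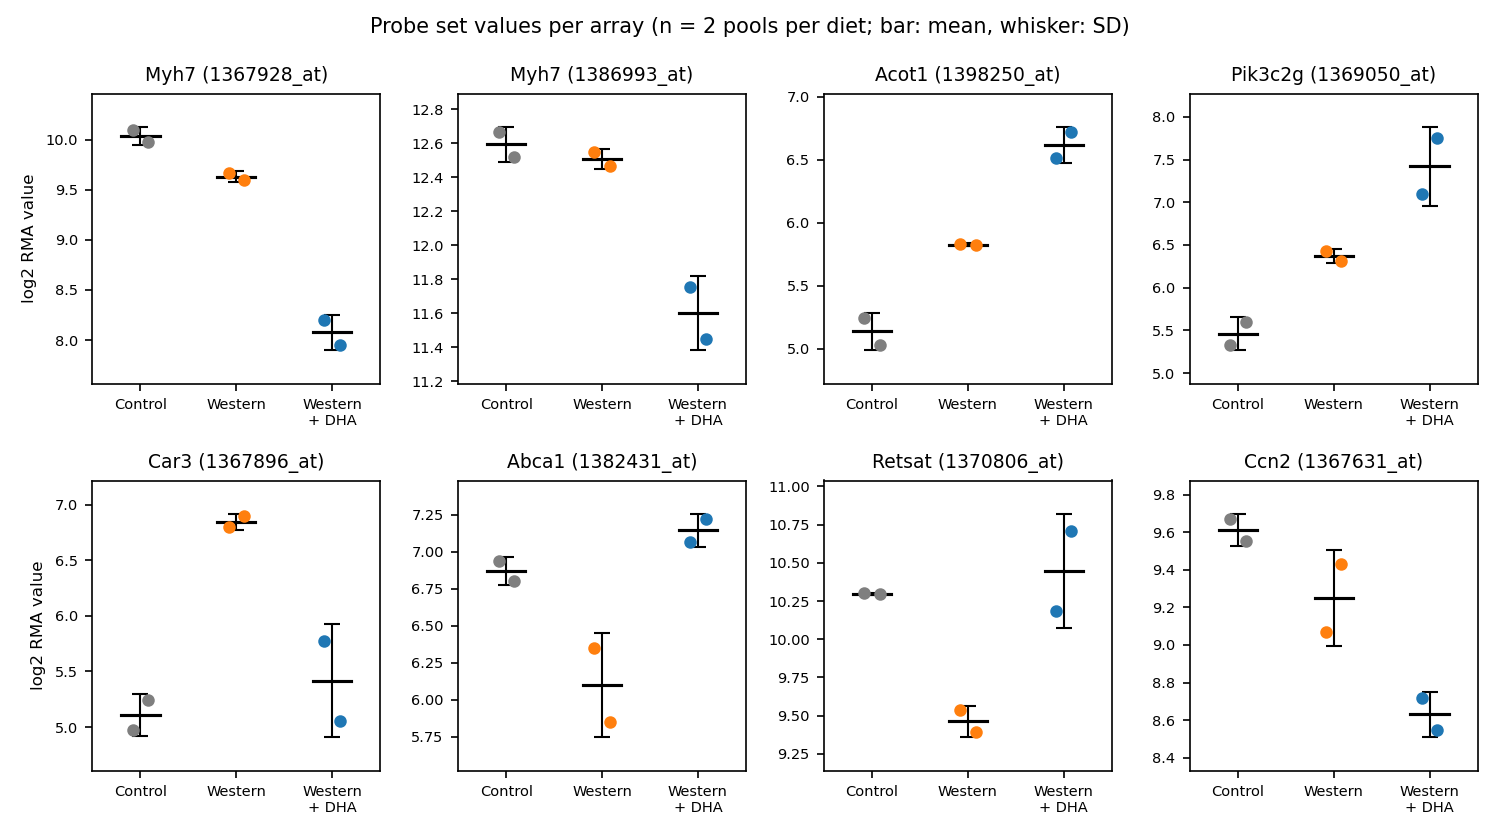
Deposited log2 RMA value (vertical axis, log scale, not starting at 0) of 8 probe sets in the 2 pools of each diet (horizontal axis), with arrays as points, means as bars and SD as whiskers. Myh7 reads 10.04 in Control and 8.08 in Western plus DHA at its called probe set, and Car3 reads 6.85 in Western against 5.11 in Control.

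Among genes that did not pass the test in Western plus DHA against Control, Acot1, which cleaves acyl-CoA and is a target of PPAR alpha, stood at 6.62 ± 0.143 (SD) against 5.14 ± 0.148 (SD), a log2 difference of 1.48 ± 0.137 (adjusted p = 0.0562). Pik3c2g, a lipid kinase of the class II PI3K family, differed by 1.96 ± 0.211 (adjusted p = 0.118). Log2 differences above 0 were also seen for Arxes1 (1.26), S100a9 (0.85), Hba-a3 (0.67), Flrt3 (0.74), Fmo2 (0.70) and Mnda (0.67). Differences below 0 were -0.98 for the matrix protein gene Ccn2, -0.89 for the calcineurin regulator Rcan1, -0.87 for Ankrd23, -0.86 for C19h1orf198, -1.15 for Rab1b, -0.64 for the collagen prolyl hydroxylase P3h1 and -0.58 for Scand1. Other probe sets differed by 0.27 and 0.08 for Fmo2, 0.16 for Mnda, -0.48, -0.57 and -0.75 for Rab1b and -0.13 for Col1a1. In the fixed panel Nppa differed by -0.22, Nppb by -0.38, Acta1 by -0.71, Ankrd1 by -0.13, Myh6 by 0.09, Col1a1 by -0.73 and Col3a1 by -0.11. The panel's metabolic genes differed by 0.59 for Angptl4, 0.31 for Scd, 0.24 for Cd36, 0.02 for Ucp3, 0.00 for Pdk4, -0.07 for Fasn and -0.24 for Cpt1b. The clock genes differed by -0.08 for Dbp and -0.32 for Bmal1. Of the 33 probe sets named for this comparison, 15 changed by more than 1.5 times or changed sign when 1 array was left out. The difference of Col1a1 was -0.06 without Control 1 and -1.40 without Control 2, and that of Angptl4 0.35 and 0.83. Acta1 had -1.15 without Western plus DHA 1 and -0.26 without Western plus DHA 2, Cpt1b -0.43 and -0.05, and Nppb -0.13 and -0.63. Myh6 lay near the top of the scale at 13.7 in Western plus DHA, and its other probe set differed by -0.81.

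Camera called 11 of the 44 lists in Western plus DHA against Control, 7 lower and 4 higher. The hypertrophic and fetal gene list was lower, with a median log2 difference of -0.22 over 15 measured members, of which 13 lay below 0 (adjusted p = 7.33e-05, and adjusted p = 0.459 with an estimated correlation). None of the representative probe sets of the 11 lists passed over all probe sets. In the hypertrophic list 2 members, Myh7 at -0.99 ± 0.14 and Rcan1 at -0.89 ± 0.15, were lower when adjusted over the list alone. Xirp1 (-0.82 ± 0.35) and the transcription factor gene Gata4 (-0.71 ± 0.29) were not. Erythroid and epicardial markers were higher in the same comparison, with list medians of 0.44 and 0.41 (adjusted p = 0.459 and adjusted p = 0.523 with an estimated correlation). The hypertrophic and heat shock lists were the 2 of the 11 that were called in each of the 6 fits that left out 1 array, and the hypertrophic median was -0.14 without Western plus DHA 1. The heat shock list was lower with a median of -0.29 (adjusted p = 0.00116, and adjusted p = 0.459 with an estimated correlation), led by Hspb7 at -0.85 ± 0.24 and the inducible Hspa1a at -0.51 ± 0.17, with 8 of 9 members below 0 and 0 passing over the list alone.

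**Figure D2:**
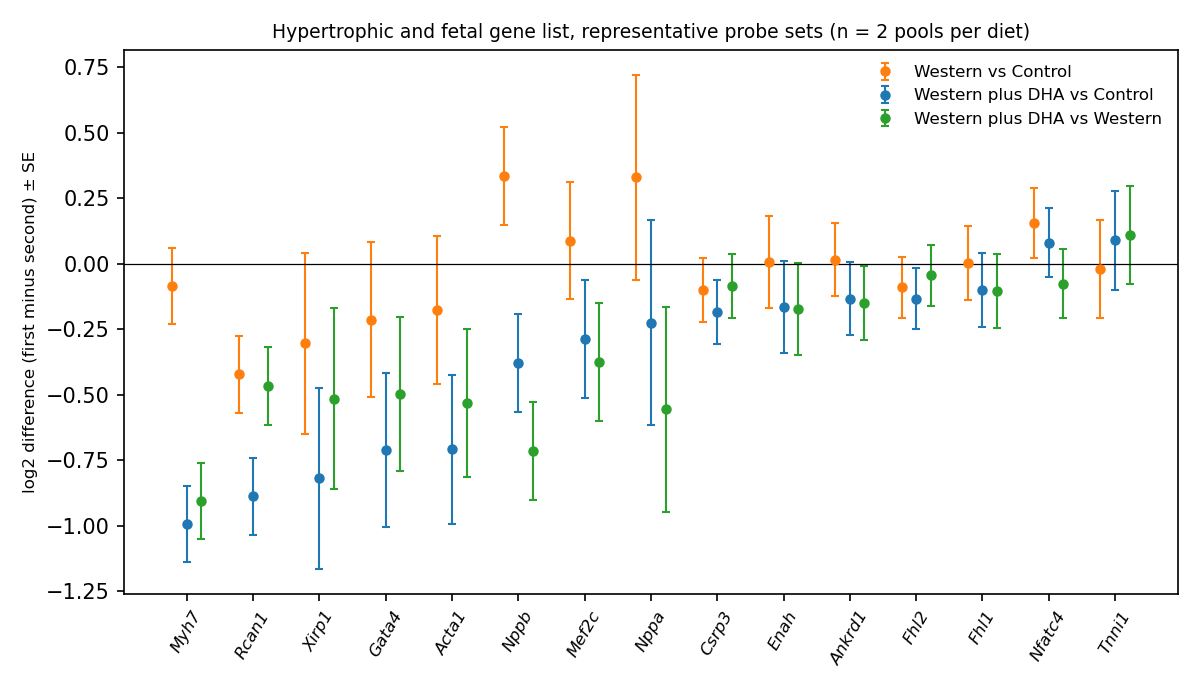
Log2 difference between diets (vertical axis, first named diet minus second) of the 15 measured genes of the hypertrophic and fetal list (horizontal axis), from 1 representative probe set per gene, with limma estimates from 2 pools per diet as points and standard errors as whiskers. Of the 15 genes, 13 lie below 0 in Western plus DHA against Control and 14 in Western plus DHA against Western.

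Immediate early genes, transcribed within minutes of a stimulus, were lower in Western plus DHA than in Control, with a median of -0.34 over 19 members (adjusted p = 0.000117, and adjusted p = 0.570 with an estimated correlation). Egr1 differed by -0.90 ± 0.27 and Nr4a1 by -1.12 ± 0.47. The glycolysis and glucose uptake list was lower with a median of -0.14 (adjusted p = 0.000525, and adjusted p = 0.570 with an estimated correlation), with the hexokinase genes Hk1 at -0.76 ± 0.19 and Hk2 at -0.47 ± 0.16. The mitochondrial biogenesis list had a median of -0.11 (adjusted p = 0.0138, and adjusted p = 0.459 with an estimated correlation), with Esrra at -0.54 ± 0.17 and Ucp2 at -1.07 ± 0.39. The tricarboxylic acid cycle list had a median of -0.08 (adjusted p = 0.0159, and adjusted p = 0.459 with an estimated correlation), with Ogdh at -0.48 ± 0.17. The glucocorticoid and fasting list had a median of -0.10 (adjusted p = 0.0473, and adjusted p = 0.653 with an estimated correlation), with Ddit4 at -0.47 ± 0.12 below 0 and Angptl4 above it. Members below 0 numbered 16 of 19 immediate early genes, 15 of 17 glycolysis genes, 12 of 15 mitochondrial biogenesis genes, 12 of 14 tricarboxylic acid cycle genes and 12 of 19 glucocorticoid genes. Of these genes 0 passed over the list alone in these 5 lists. Without Control 1 the calls of the immediate early, glycolysis, mitochondrial biogenesis and glucocorticoid lists were lost. The log2 difference between 3' and 5' probe sets was largest in that array for the poly-A controls (1.75, others 1.36 to 1.42) and Gapdh (0.68, others 0.30 to 0.47), while that of beta-actin was 1.82 there and 1.87 in Western plus DHA 1. Whether this bears on these lists was not tested. The mitochondrial biogenesis and tricarboxylic acid lists lost theirs without Western plus DHA 1, the tricarboxylic acid list also without Control 2, and the glucocorticoid list also without Western plus DHA 2. The highest adjusted p in these fits was 0.0976 for the immediate early list, 0.0683 for glycolysis, 0.113 for both mitochondrial lists and 0.730 for the glucocorticoid list. Medians lay between -0.53 and -0.08 for immediate early genes, -0.32 and -0.06 for glycolysis and -0.19 and 0.01 for the glucocorticoid list, the first without Control 2 and the second without Control 1. The mitochondrial biogenesis median was -0.22 without Control 2.

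Of the 13 cell type lists 2, epicardial and erythroid, were called higher in Western plus DHA than in Control, as were 2 programme lists. The epicardium and mesothelium list had a median of 0.41 over 9 members, all above 0 (adjusted p = 0.00116, and adjusted p = 0.523 with an estimated correlation). Its leading members were the mesothelial surface gene Msln (0.47 ± 0.12) and the keratin gene Krt19 (0.82 ± 0.23), and 4 members were higher when adjusted over the list alone. Krt19 read 3.88 and Msln 5.20 in Western plus DHA, below the median of all probe sets of 5.34. The erythroid list had a median of 0.44 over 6 members (adjusted p = 0.0138, and adjusted p = 0.459 with an estimated correlation), with the globin chaperone Ahsp at 0.79 ± 0.19 and beta globin Hbb at 0.51 ± 0.13, and 4 members were higher when adjusted over the list alone. The eicosanoid and phospholipase list had a median of 0.25 (adjusted p = 0.0138, and adjusted p = 0.523 with an estimated correlation), led by the secreted phospholipase Pla2g2a (0.58 ± 0.14) and the prostaglandin D synthase Ptgds (0.59 ± 0.16), with 12 of 16 members above 0 and 2 higher when adjusted over the list alone. The inflammatory list had a median of 0.14 (adjusted p = 0.0217, and adjusted p = 0.653 with an estimated correlation), led by S100a9 and Cxcl1 (0.44 ± 0.17), with 17 of 20 members above 0 and 1 higher when adjusted over the list alone. These 4 calls were lost without Control 2, and those of the epicardial, eicosanoid and inflammatory lists also without Western plus DHA 1. The highest adjusted p values were 0.143 for epicardium, 0.212 for erythroid cells, 0.373 for eicosanoid genes and 0.996 for the inflammatory list. Without Western plus DHA 1 the medians were 0.21 for the epicardial list, 0.15 for the eicosanoid list (0.15 also without Control 1) and 0.04 for the inflammatory list, which had 0.28 without Western plus DHA 2.

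**Figure D3:**
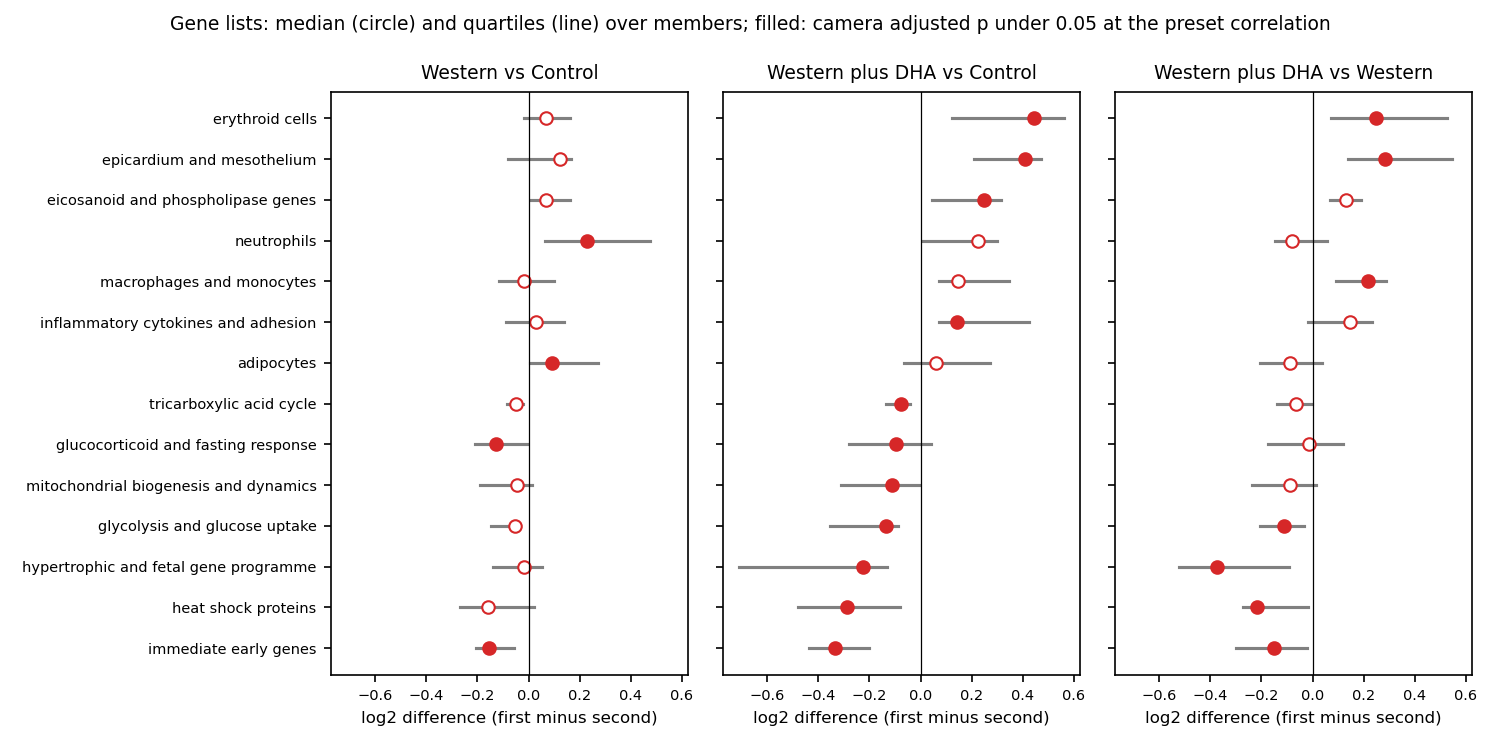
Median (circle) and quartiles (line) of the log2 difference over the members of the 14 gene lists called in at least 1 comparison (horizontal axis, first named diet minus second, 1 panel per comparison), filled where the camera adjusted p was under 0.05 at the preset correlation. The hypertrophic and fetal list has a median of -0.22 against Control and -0.38 against Western in Western plus DHA, and with an estimated correlation no list was called.

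The comparison of Western plus DHA with Western asked what the supplement changed on the Western diet. The dimmer probe set of Myh7 read 8.08 ± 0.176 (SD) against 9.63 ± 0.0520 (SD), a log2 difference of -1.56 ± 0.137 and a 2.94-fold lower level, with an adjusted p of 0.0740 that did not pass the test. Its brighter probe set differed by -0.91 ± 0.145. Abca1 and Retsat, which had values below Control in Western, differed from Western by 1.05 ± 0.177 and 0.98 ± 0.178 in Western plus DHA, and Car3 differed by -1.43 ± 0.223. The comparisons of Western with Control and with Western plus DHA share the Western arrays. An error in those arrays alone would give differences of opposite sign, so these values do not show a reversal by the supplement. Other probe sets differed by 0.11, 0.40 and 0.79 for Abca1 and by -0.19 for Car3. The limma test called 0 of 31042 probe sets, with a lowest adjusted p of 0.0740, and 1261 lay under an unadjusted p of 0.05 where chance gives 1552.1. Of these 49.1% were higher in Western plus DHA, against 33.4% without dim probe sets, 57.5% without Western plus DHA 2 and 58.9% with representative probe sets. There were 476 such probe sets without Western 2 and 2392 without Western plus DHA 1. Further log2 differences above 0 were those of Acot1 (0.79), Ctsm (0.93), Pik3c2g (1.05), the phosphatidylcholine carrier Pctp (0.61), the sterol synthesis gene Idi1 (0.60) and Arxes1 (0.73). Differences below 0 were those of Hipk3 (-0.63), Ccn2 (-0.62), Ddah1 (-0.50), Adra1d (-0.56), Ankrd23 (-0.60) and Nppb (-0.72), and none of these passed the test. Other probe sets differed by 0.14 and -0.01 for Hipk3 and by 0.15 for Idi1. The other panel genes differed by -0.56 for Nppa, -0.53 for Acta1, -0.15 for Ankrd1, 0.03 for Myh6, -0.18 for Col1a1, -0.01 for Col3a1, 0.05 for Pdk4, -0.19 for Ucp3, -0.27 for Cpt1b, 0.30 for Angptl4, -0.06 for Cd36, -0.18 for Scd, 0.01 for Fasn, 0.09 for Dbp and -0.30 for Bmal1. Of the 32 probe sets named for this comparison, 15 changed by more than 1.5 times or changed sign when 1 array was left out. Nppb had -0.47 without Western plus DHA 1 and -0.96 without Western plus DHA 2, Acta1 -0.97 and -0.09, and Cpt1b -0.46 and -0.08.

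Camera called 7 of the 44 lists in Western plus DHA against Western, 4 lower and 3 higher. The hypertrophic and fetal list was lower with a median of -0.38, and 14 of its 15 members lay below 0 (adjusted p = 8.17e-06, and adjusted p = 0.503 with an estimated correlation). When adjusted over the list alone 2 members were lower, Myh7 at -0.91 ± 0.14 and the natriuretic peptide gene Nppb at -0.72 ± 0.19. The hypertrophic list was the 1 of the 7 that was called in each of the 6 fits that left out 1 array, with a median of -0.21 without Western 2 and -0.21 without Western plus DHA 2. The glycolysis list was lower with a median of -0.11 (adjusted p = 0.00913, and adjusted p = 0.668 with an estimated correlation), with Hk1 at -0.61 ± 0.19. The immediate early list was lower with a median of -0.15 (adjusted p = 0.0193, and adjusted p = 0.668 with an estimated correlation), with Ier3 at -0.44 ± 0.15. The heat shock list was lower with a median of -0.22 (adjusted p = 0.0485, and adjusted p = 0.668 with an estimated correlation), with Hspb1 at -0.32 ± 0.12. The epicardial list was higher with a median of 0.28 (adjusted p = 0.000694, and adjusted p = 0.668 with an estimated correlation), with Msln at 0.42 ± 0.12 and Lrrn4 at 0.55 ± 0.16. The macrophage list was higher with a median of 0.22 (adjusted p = 0.0122, and adjusted p = 0.668 with an estimated correlation), with Fcgr2b at 0.56 ± 0.16 and Lyz2 at 0.38 ± 0.16. The erythroid list was higher with a median of 0.25 (adjusted p = 0.0193, and adjusted p = 0.668 with an estimated correlation), with Hemgn at 0.69 ± 0.15. Over all probe sets 0 members of the 7 lists passed, and over the list alone 2 epicardial and 2 erythroid genes were higher. Without Western plus DHA 1 the epicardial (adjusted p = 0.351), macrophage (0.800), erythroid (0.0593) and heat shock (0.475) calls were lost, and the macrophage median became -0.09. The immediate early call was lost without Western 2 or Western plus DHA 2 and the glycolysis call without Western plus DHA 2, with highest adjusted p values of 0.144 and 0.0505. The macrophage call was lost without Western 2 too, and the heat shock and erythroid calls without Western 1. Without Western plus DHA 2 the medians were 0.45 for macrophages, -0.05 for immediate early genes and -0.07 for heat shock proteins. Without Western plus DHA 1 they were -0.29 for immediate early genes and -0.21 for glycolysis.

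The other 30 lists were called in none of the 3 comparisons, with lowest adjusted p values of 0.0717 in Western against Control, 0.0564 in Western plus DHA against Control and 0.0888 in Western plus DHA against Western. In Western plus DHA against Control the list medians of cell type markers were -0.22 for smooth muscle and pericytes, -0.05 for endothelial cells, 0.00 for atrial cardiomyocytes, 0.02 for nerve and Schwann cells, 0.10 for fibroblasts, 0.10 for skeletal muscle, 0.15 for mast cells and 0.20 for lymphocytes. The medians of metabolic lists were -0.12 for insulin signalling, -0.09 for cholesterol synthesis and uptake, -0.02 for oxidative phosphorylation subunits, 0.00 for lipid uptake and storage, 0.01 for mitochondrial fatty acid oxidation, 0.01 for fatty acid synthesis, 0.07 for the hexosamine pathway, 0.08 for PPAR alpha target genes and 0.11 for peroxisomal lipid metabolism. Of the 23 measured PPAR alpha target genes, 1 (Acot1) was higher when adjusted over the list alone, as was 1 mast cell gene, and 1 matrix gene was lower. The medians of the remaining lists were -0.11 for autophagy and protein breakdown, -0.08 for potassium and sodium channels, -0.07 for contractile and calcium handling genes, -0.06 for extracellular matrix and fibrosis, -0.06 for antioxidant genes, -0.06 for the hypoxia response, 0.00 for apoptosis, 0.02 for renin-angiotensin and adrenergic signalling, 0.02 for the circadian clock, 0.05 for the interferon response, 0.05 for the cell cycle, 0.10 for the unfolded protein response and 0.12 for cytosolic ribosomal proteins. Median, mean and test differed in sign for the interferon, fatty acid oxidation, fatty acid synthesis, clock, renin-angiotensin, apoptosis, atrial and skeletal muscle lists in this comparison.

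Differences of both Western diets from Control were compared across 14217 genes, which are not independent replicates. The log2 differences had a Pearson r of 0.625 and a Spearman rho of 0.603, and 71.4% of genes had the same sign. Unchanged groups simulated against the same control arrays gave a mean r of 0.50 and a highest r of 0.521 over 200 simulations. The noise was drawn independently for each gene, so deviations that many genes of an array share could make all simulated ranges here too narrow. The simulations also gave the 3 diets the same spread per gene. The SD of the difference between the 2 arrays of a diet was 0.286 for Control, 0.201 for Western and 0.280 for Western plus DHA. A larger spread in Control than in Western raises r and covariance for unchanged diets. An excess over these simulations can therefore not be assigned to a shared effect of diet. The covariance was 0.0217 against a simulated 0.0128, a difference of 0.00888. The simulated share of genes with the same sign was 66.6% (65.5% to 68.1%). At an unadjusted p under 0.05, 72 genes were higher and 35 lower in both comparisons. Independent lists would share 8.83 and 3.35, but the lists share their controls. Unchanged groups simulated with the same controls shared means of 78.2 (55 to 111) and 78.2 (56 to 102). The observed 35 lay below all simulations, so these did not match the data there. In the data 2.83% and 8.87% of all probe sets lay under this p in the 2 comparisons, shares that the simulations were not set to reproduce. The comparison is thus rough, and the overlaps give no evidence of a shared effect of diet. The controls were not split, since each comparison would keep 1 control array. With 1 array left out, r was 0.490 without Control 1 and 0.852 without Control 2, against simulated means of 0.666 and 0.666. It was 0.398 without Western 1, inside the simulated 0.385 to 0.433, 0.648 without Western 2, 0.529 without Western plus DHA 1 and 0.551 without Western plus DHA 2, against simulated means of 0.407 to 0.408. An r above that of the simulated groups thus depended on Control 1 and on Western 1.

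The authors' deposited table gave log2 differences that differed by at most 5e-08 from differences of the diet means in all 3 comparisons. By the authors' adjusted p under 0.05 it held 0 probe sets for Western against Control, 1 for Western plus DHA against Control and 0 for Western plus DHA against Western. The authors' deposited list of 66 probe sets, 2 of them Affymetrix controls, held the same 66 probe sets as those with a p of theirs under 0.001 in any comparison, 56 of them in Western plus DHA against Control. That p was not adjusted for the number of probe sets, and 1 of the 66 passed the adjusted threshold.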

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

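The tests of cell share, of blood and of how far cyclic loess moved the hypertrophic list were chosen after the results were seen. The poly-A spike-in control probe sets, which lie outside the main measurement, had a median log2 difference of 0.43421 between Western plus DHA and Control, with 24 of 24 probe sets higher, and array medians of 10.7 and 11.3 in Control against 11.4 and 11.4 in Western plus DHA. The beta-actin control probe sets had a median log2 difference of 0.287723 between Western and Control over 3 probe sets, which lie outside the main measurement too, -0.15 between Western plus DHA and Control and -0.44 between Western plus DHA and Western. The 3 hexokinase control probe sets had a median log2 difference of -0.88 between Western plus DHA and Control. The log2 difference between the 3' and 5' probe sets of the poly-A controls was 1.75 in Control 1 against 1.36 to 1.42 in the other 5 arrays, and that of Gapdh was 0.68 against 0.30 to 0.47. That of beta-actin was 1.82 in Control 1, 1.87 in Western plus DHA 1 and 1.48 to 1.54 in the others, and that of hexokinase lay between 1.89 in Control 2 and 2.28 in Control 1.

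The first pattern is the lower hypertrophic and fetal gene list in Western plus DHA than in Western. A single array as its whole source is argued against, since the list median was at most -0.209 when each of the 6 arrays was left out in turn. Leaving out a Control array cannot move this difference, so only the Western and Western plus DHA arrays were tested. The median was -0.375 with all arrays, -0.21 without Western 2 and -0.21 without Western plus DHA 2. A part played by a single array thus stays open. Compression of intensities across an array as the whole source is argued against, since cyclic loess moved the members by a median of 0.00973. A move of 0.275 would bring the list median to -0.1. The bootstrap 95% interval of the move, 0.00968 to 0.00981, is over members and leaves out the spread between arrays. Medians of 10 bins by intensity differed by at most 0.0361 between these diets, so the small move followed from a small trend. A part played by compression stays open by the bound set beforehand: after cyclic loess the median was -0.365, against -0.375 before, and the list was still called at the preset correlation, but its bootstrap 95% interval over members, from -0.522 to -0.0729, reached past that bound of -0.1. In Western against Control the median of this list was -0.0198 and the list was not called, so no rise on the Western diet was seen. An effect of the supplement on this list is a hypothesis that the 2 pools per diet do not settle, and the call against Western was lost with an estimated correlation.

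The second pattern is the higher epicardial and erythroid markers in Western plus DHA than in Control. Both calls were lost with an estimated correlation (camera adjusted p = 0.523 and 0.459). Without Western plus DHA 1 the epicardial median was 0.21, against 0.41 with all arrays. More blood in these pools and an effect of diet cannot be told apart for the erythroid part: the 2 globin probe sets at or above the median level, Hbb at 12.7 and Hba-a3 at 10.3 on average, had a median log2 difference of 0.591 and the other erythroid genes one of 0.380, values already seen when the test was written. Blood was not tested as a source of the epicardial part. A lower share of heart muscle would raise the markers of other cell types alike, and the epicardial median exceeded the endothelial one by 0.462 (bootstrap 95% interval 0.0745 to 0.777), the smooth muscle one by 0.629 (0.220 to 0.886) and the fibroblast one by 0.311 (-0.0179 to 0.604). These intervals leave out the spread between arrays, and the endothelial one missed the bound of 0.1, so a changed cell share and an effect of diet cannot be told apart for the epicardial markers.

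The third pattern is the 2752 probe sets past an unadjusted p of 0.05 in Western plus DHA against Control, where chance gives 1552.1. That chance count assumes 1 spread for all diets. The SD of the difference between the 2 arrays was 0.286 for Control, 0.201 for Western and 0.280 for Western plus DHA. The smaller spread of Western lowers the shared estimate, so chance could give more than 1552.1. With array weights the count was 1993. Intensity compression as the whole source is argued against, since 2520 lay past an unadjusted p of 0.05 after cyclic loess, still above 1552.1. Whether separate pools share the differences stays open: across genes, the differences of 2 separate array pairs correlated at 0.291 when paired by number and at -0.0118 when paired the other way, after cyclic loess. Without Control 1 the count was 1314, below chance, and without Control 2 it was 4955. Chance could not be excluded for the 11 lists called in this comparison. Of the 45 splits of the 6 arrays into pairs, 9 called as many lists, the real one included, and the highest of the others called 15. Some of these splits keep part of the diet contrast, but of the 6 whose pairs held the same diets 2 called as many, with a highest of 12. Among these 6, splits of number 1 against number 2 arrays called 7, 11 and 12 lists, and crossed ones 4, 1 and 5. Whether the replicate numbers mark a batch behind these counts is not settled.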

How the results depend on the processing

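Cyclic loess and the fit without Control 1 and Western plus DHA 2 together were chosen after seeing the data, and the causes of the changes below were not tested unless given. Among the named genes, 1640 results kept their direction and side of the threshold under an alternative, 8 fell short of the threshold, 6 passed it and 62 reversed. Before any alternative, all named results but that of the dimmer Myh7 probe set in Western plus DHA against Control had missed the threshold. Several alternatives, such as the priors, also leave a log2 difference unchanged, so the 1640 do not measure stability. Among the called lists 218 were kept, 103 were lost and 4 reversed. The count of 1 probe set in Western plus DHA against Control was 0 with representative probe sets only, since the called Myh7 probe set is not the representative one, 0 without Control 1 and Western plus DHA 2 together, 0 with only the 4 arrays compared (fewer arrays), 2 at an adjusted p under 0.1, and 0 to 2 (2 without Western plus DHA 1) when 1 array was left out. The count of 0 in Western plus DHA against Western was 1 with quantile normalization again, median centring, an intensity trend, array weights or an adjusted p under 0.1. The F test's count of 1 was 0 with representative probe sets only, 0 without Control 1 and Western plus DHA 2 together, and 0 to 0 when 1 array was left out. The count of 4 lists in Western against Control was 0 with an estimated correlation, 0 with fry, 1 without dim probe sets, 2 after cyclic loess, 1 without the 2 arrays, and 1 (without Control 1) to 7 (without Western 2) when 1 array was left out. The 11 lists in Western plus DHA against Control were 0 with an estimated correlation, 3 with fry, 6 without dim probe sets, 7 with quantile normalization again, 7 after cyclic loess, and 7 (without Control 2) to 15 (without Western plus DHA 2) when 1 array was left out. The 7 lists in Western plus DHA against Western were 0 with an estimated correlation, 0 with fry, 1 without dim probe sets, 11 with the mean of a gene's probe sets, 15 without the 2 arrays, and 5 (without Western plus DHA 1) to 12 (without Western plus DHA 2) when 1 array was left out. These list counts are of all lists called under an alternative and can include lists not called in the main fit. Without dim probe sets, the 1 list called in Western against Control was not among the 4. In Western plus DHA against Control, 5 of the 6 lists called there were among the 11. The correlation of fold changes lay between 0.398 and 0.852 when 1 array was left out. The replicate block left the probe set counts at 0, 1 and 0, with lists at 4, 11 and 6. Same-numbered arrays deviated from their diet means with correlations across probe sets of -0.206 for Control and Western, 0.202 for Control and Western plus DHA and -0.228 for Western and Western plus DHA, which does not settle whether the numbers mark a shared batch. Without Control 1 and Western plus DHA 2 together, log2 differences changed sign for values that had not passed the test and for 2 lists. In Western against Control these were Acta1 at 0.0451, Ankrd1 at -0.141, Col1a1 at 0.114, Col3a1 at 0.097, Bmal1 at 0.299 and immediate early genes at 0.0857. For Western plus DHA against Control they were Myh6 at -0.00143, Col1a1 at 0.0851, Col3a1 at 0.333, Pdk4 at -0.0712, Cpt1b at 0.124, Bmal1 at 0.319 and glucocorticoid and fasting response at 0.0543. For Western plus DHA against Western they were Myh6 at -0.00169, Col3a1 at 0.236, Pdk4 at -0.0399, Cd36 at 0.019 and Bmal1 at 0.0202. Other probe sets of a gene had the opposite sign. In Western against Control these were Myh6 at -0.393, Ankrd1 at -0.116, Col1a1 at 0.157 and Pdk4 at 0.0875. The values for Western plus DHA against Control were Myh6 at -0.805, Pdk4 at -0.161, Ucp3 at -0.248 and Fasn at 0.108. The values for Western plus DHA against Western were Hipk3 at 0.138, Myh6 at -0.412 and Pdk4 at -0.249. With quantile normalization again the sign changed for Bmal1 at 0.00642 in Western against Control and Col3a1 at 0.0264 in Western plus DHA against Western. Leaving out 1 array gave ranges across 0. In Western against Control these were Acta1 from -0.397 to 0.0451, Ankrd1 from -0.141 to 0.173, Bmal1 from -0.335 to 0.299, Col1a1 from -1.23 to 0.114, Col3a1 from -0.294 to 0.097, Cpt1b from -0.142 to 0.206, Fasn from -0.172 to 0.0186, immediate early genes from -0.39 to 0.0857 and Nppa from -0.381 to 1.04. Ranges for Western plus DHA against Control were Ankrd1 from -0.29 to 0.0238, Bmal1 from -0.633 to 0.0021, Cd36 from -0.036 to 0.509, Col3a1 from -0.364 to 0.138, Fasn from -0.161 to 0.029, glucocorticoid and fasting response from -0.19 to 0.0131, Nppa from -0.474 to 0.0249, Pdk4 from -0.0871 to 0.0964 and Ucp3 from -0.0705 to 0.114. Ranges for Western plus DHA against Western were Bmal1 from -0.615 to 0.0202, Cd36 from -0.133 to 0.019, Col3a1 from -0.265 to 0.236, Dbp from -0.0154 to 0.198, Fasn from -0.0713 to 0.092, macrophages and monocytes from -0.0891 to 0.447, Myh6 from -0.00169 to 0.0569, Nppa from -1.27 to 0.157 and Pdk4 from -0.0399 to 0.144. Where an array was left out, the lone array of its diet is assumed to vary like the others. Without dim probe sets 9 of the 44 lists had too few members to be tested, so that 1 call in Western against Control (neutrophils), 2 in Western plus DHA against Control and 2 in Western plus DHA against Western (epicardial and erythroid) were not tested there rather than lost. Low signal limits the dim ones among these markers, while Hbb at 12.7 and S100a9 at 6.30 on average lay above the median of 5.34. Of 10 bins by intensity, the third from the dimmest had a median log2 difference of 0.08 between Western plus DHA and Control. That is below the epicardial and erythroid list medians of 0.41 and 0.44, and its bearing on these lists was not tested.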

Other observations

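None of the genes in this paragraph passed the test. Abca1 read 6.87 ± 0.0967 (SD) in Control, 6.10 ± 0.354 (SD) in Western and 7.15 ± 0.110 (SD) in Western plus DHA, and Retsat read 10.30 ± 0.00452 (SD), 9.46 ± 0.103 (SD) and 10.45 ± 0.372 (SD). Car3 read 5.42 ± 0.507 (SD) in Western plus DHA against 5.11 ± 0.188 (SD) in Control. For Abca1, Retsat and Car3 the differences of Western from both other diets rest on the same Western arrays, so they are not independent. Each array of Western lay above both of Control, and each of Western plus DHA above both of Western, for Acot1 and Pik3c2g. The rule named both genes in every comparison and required arrays to lie apart, so this order followed from selection. Arxes1, Flrt3, Fmo2, Mnda and Hba-a3 had the same order. The reverse order held for Ccn2, Rcan1, Ankrd23, C19h1orf198, P3h1, Scand1, Phlda1 and Card9. The rule named each of these genes in a comparison for which it required arrays to lie apart, so part of their order followed from selection too. Of 14217 genes, arrays lay apart in either direction for 28.4% in Western against Control. The shares were 36.6% in Western plus DHA against Control and 36.8% against Western, where chance gives 33.3%.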
